A study of Homo sapiens with 3 samples.

How the data were processed

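Droplet-based single-cell RNA sequencing was done on 3 libraries of the PGP1 stem cell line carrying an inducible GATA6, 1 library for each of the pools of day 0 with day 3, day 0 with day 5 and day 0 with day 8. Per the labels, cells were released with trypsin and collagenase, and libraries were made with the single cell 3' v2 chemistry of 10x Genomics. The deposited matrices hold counts: whole numbers of UMIs per gene and barcode, not normalized by the authors, whose notes name Cell Ranger 2.1.1 and the GRCh38 genome. The other deposited files hold other content, namely the gene identifiers and the cell barcodes that name the rows and columns. The deposited barcodes have 12 bases, whereas v2 barcodes have 16, and the labels do not explain this. The libraries hold 1999, 1957 and 1999 barcodes and 38702, 31480 and 33865 genes. Of these genes, 38698, 31478 and 33861 matched GENCODE 29 by identifier with version, and the other 4, 2 and 4 are introduced sequences, among them rtTA3 and EYFP. The matrices hold 12076067, 8322589 and 15427588 UMIs, of which kept cells hold 10940253, 7357124 and 14426086. This puts 1 UMI of the kept cells at 0.0914 CPM in D3, 0.136 CPM in D5 and 0.0693 CPM in D8.

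Barcodes were kept with at least 500 genes, at least 1000 UMIs and under 20% mitochondrial UMIs. In the 3 libraries in turn, 139, 1026 and 55 barcodes missed the gene or UMI minimum and 308, 204 and 219 more missed the mitochondrial limit. Scrublet, as run by scanpy 1.11.5 with 6% expected doublets, removed 16 more. Kept cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0). This gave 12 clusters over the 3 libraries together, without batch integration. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with edgeR 4.0.16 under R 4.3.3 for TMM factors.

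Clusters were named from 15 cell type marker lists. A marker was carried by a cluster where it reached 20 CPM, at least 0.67 of its highest level over clusters and at least 2 times its median over clusters, and a name needed at least 3 carried markers. The lists were fixed before the data were examined, but this scoring rule was settled after clusters had been seen, since earlier forms named a mixed D8 cluster hepatic or left pluripotent clusters without a name. It took the definitive and the yolk-sac endoderm lists as 1 class, endoderm-like. It named 8 clusters and left clusters 1, 2, 8 and 10 unnamed. A cluster of 16 barcodes of D5 named endoderm-like shared its first 10 bases in every barcode. Cluster 5 met the rule for the mesenchymal list, but is named by number in the text.

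Design, filters, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. For each pair of libraries, log2 ratios of CPM of summed counts were computed with exact conditional-binomial 95% intervals. Named genes were the 15 higher and 15 lower genes whose interval lay farthest from 1, among genes in both files with a mean of at least 20 CPM. Some genes of these sets are not reported here. Mitochondrial and ribosomal protein genes, unnamed clones, XIST and Y-linked genes were left out of that choice. Between classes, 10 genes each way were named outside the naming markers. The 15 type lists and 18 pathway lists were described by the median over members with a mean of at least 5 CPM, where at least 5 were measured, with a percentile among 10000 random lists matched on expression. A member with a count of 0 on one side was set at the bound that 3 counts give. That step was added after a first run. It raised medians that include such members, for D8 over D3 those of the foregut and hepatic and the plasma protein lists. Levels have exact Poisson intervals and shares exact Clopper-Pearson intervals. No test was made, because each group has 1 library and cells are not replicates. Thinning drew 1500 UMIs from each cell, which 1515, 676 and 1702 cells of the libraries had.

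The intervals and the rule for named genes were tested on simulated data, drawn as Poisson counts from the mean profile of each pair with known folds. For D5 over D3, intervals covered an imposed 2-fold change in 100% and an imposed 4-fold change in 96% of 50 genes. The lowest coverage was 92%, for 0.5-fold in D8 over D3. Intervals excluded 1 for 6.29% of unchanged genes in D5 over D3 and 7.21% in D8 over D5. For D5 over D3, all 30 named genes were ones that had been changed. Poisson draws hold counting error only, so the spread between cells or libraries was not tested. Alternatives tried were other clustering settings, other filters, thinning, each library alone, TMM and median-of-ratios scaling, means over cells, every deposited barcode, other expression minimums, and cells outside pluripotent-like clusters. Chosen after the data had been seen were the merging of neighbouring barcodes, named clusters only, clustering without GATA6 and the introduced sequences, the mitochondrial share without ribosomal RNA, which class contrasts to give, and the comparisons of 1 class between libraries other than the pluripotent-like class. Cells could not be assigned to days, and no reads were available, so the transgene could not be traced by sequence.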

Results

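Single-cell transcriptomes were collected from a human induced pluripotent stem cell line, PGP1, in which the transcription factor GATA6 can be switched on by an inducer. The study uses such cultures as liver organoids. Per the labels, the inducer was present from day 0 to day 5, after which it was withdrawn and the medium changed. Each of the 3 libraries pools cells of day 0 with cells of 1 later day, and they are called here the D3, D5 and D8 libraries. The files do not say which cell came from which day. Each group holds 1 library, so there are no replicates, and every interval given here covers counting error only. The deposited matrices hold 12076067 UMIs over 1999 barcodes in D3, 8322589 over 1957 in D5 and 15427588 over 1999 in D8. After filtering, 1548, 723 and 1717 cells were kept, with a median of 4710, 4322 and 5602 UMIs per cell.

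The first question was how the level of the induced factor differed between the libraries. GATA6 RNA was abundant in the libraries taken while the inducer was present and low in the D8 library, taken after it had been withdrawn. GATA6 (ENSG00000141448.8, GRCh38 chromosome 18, 22169443 to 22202528, plus strand, a protein-coding gene) stood at 515 CPM (UMIs scaled to a total of 1000000) in D3, with an exact Poisson 95% interval of 501 to 528. It stood at 944 CPM (922 to 966) in D5 and at 77.7 CPM (73.2 to 82.4) in D8. The D8 level was 12.1-fold lower than that of D5 (11.4 to 12.9) and 6.62-fold lower than that of D3 (6.21 to 7.07). D5 over D3 was 0.87 on the log2 scale. GATA4 was likewise highest in D5, at 108 CPM, but stood higher in D8 (54.8 CPM) than in D3 (35.6 CPM). A GATA6 UMI was seen in 75.4% of kept cells in D3, 64.7% in D5 and 33.7% in D8. With all cells thinned to 1500 UMIs these shares were 47.9%, 49.9% and 9.81%. Each library pools day 0 with a later day in an unknown proportion, so these are levels of pools and not of single days. In the endoderm-like class defined below, which GATA6 helped form, D3 stood higher (2525 CPM) than D5 (1496 CPM). Transgenic and endogenous GATA6 transcripts could not be separated, because the row for the GATA6-puromycin construct held 1 UMI in D3, 1 UMI in D8 and was absent from the D5 file.

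Cells of the 3 libraries were then sorted into classes by marker genes, to ask which cell types accompanied GATA6 in each library. Pluripotent-like cells were present in every library, and endoderm-like cells were the main named class of D5. Hepatic-like cells were mostly of D8, although clustering each library alone also formed them in D5. The main endoderm-like cluster carried 6 markers of the definitive and 6 of the yolk-sac endoderm list, so its name does not tell these apart. The hepatic-like cluster carried 12 hepatic and 9 yolk-sac markers, from lists that share members such as AFP and TTR. The streak-like cluster, with the streak markers TBXT, MIXL1 and EOMES, was mostly of D5. It carried 6 markers of the streak list and 5 of the mesoderm list, so its name is a near tie. An endothelial-like cluster with PECAM1, CDH5 and CD34 was mostly of D8. One further cluster, cluster 5, carried collagen genes such as COL1A1, COL3A1 and COL6A1 together with the cardiac gene ACTC1. None of its leading genes was a marker of the mesenchymal list that its collagens belong to, and it is named by number. The leading genes of the endoderm-like clusters held no marker of their lists either. That name was kept, and rests on carried markers alone. The leading gene of cluster 5, HBB, rests on 3 barcodes, which held 468 of the 475 HBB UMIs of D8.

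Endoderm-like cells made up 4.78% of kept cells in D3 (exact Clopper-Pearson interval 3.77 to 5.96), 53.4% in D5 (49.7 to 57.1) and 0.582% in D8. Hepatic-like cells made up 19.0% in D8 (17.2 to 21.0), against 1 cell in D5 (63 cells, 8.71%, with D5 clustered alone) and 0 of 1548 in D3, which allows a share of up to 0.194%, taken as 3 counts of the total. Pluripotent-like cells made up 17.7% in D3 (15.8 to 19.7), 17.8% in D5 (15.1 to 20.8) and 7.63% in D8 (6.42 to 8.99). Streak-like cells made up 12.3% in D5 (10.0 to 14.9), cluster 5 made up 2.07%, 13.1% and 8.21% of the 3 libraries in turn, and endothelial-like cells 1.75% in D8 (1.18 to 2.48). Clusters that no marker list named took 75.0% of D3 (72.8 to 77.1), 3.04% of D5 and 62.0% of D8 (59.6 to 64.3). Their median mitochondrial share was 13.9% in D3 and 14.4% in D8, against 6.70% in the pluripotent-like cells of D3. Since the mixing of days can set the number of pluripotent-like cells, shares were also taken among named cells outside that class. Endoderm-like cells were then 65.5% of D3 (74 of 113 cells) and 67.5% of D5 (386 of 572), and hepatic-like cells 62.6% of D8 (327 of 522). These shares leave out the unnamed cells, 1161 in D3, 22 in D5 and 1064 in D8. That of D3 thus rests on few of its 1548 kept cells, and the likeness of D3 and D5 does not extend to the whole libraries.

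**Figure D1:**
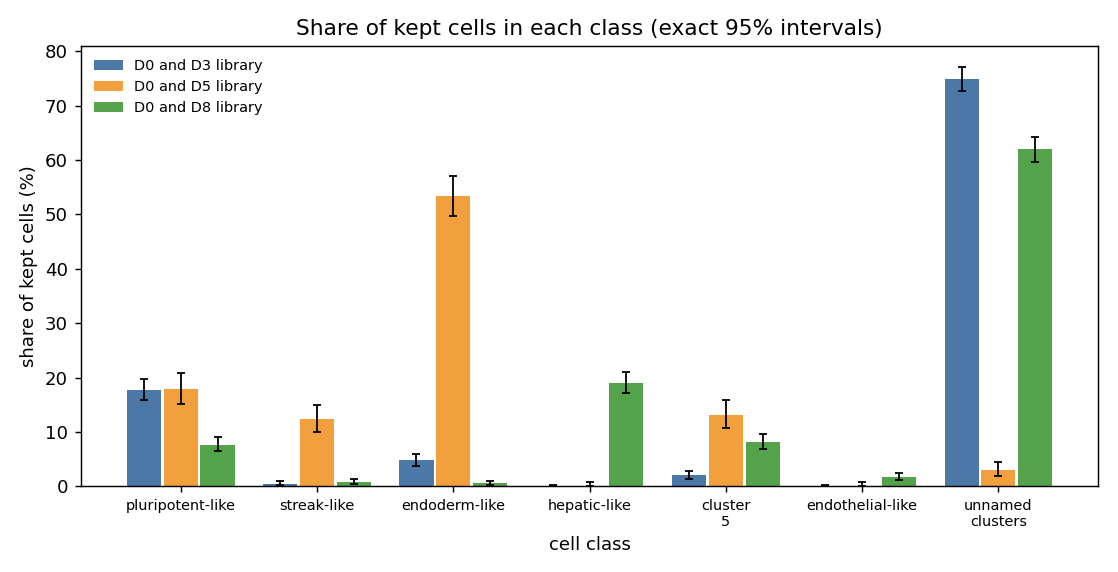
Share of kept cells (%, from 0) in each class, 1 bar per library, with exact 95% binomial intervals. Endoderm-like cells reach 53.4% in D5, hepatic-like cells 19.0% in D8, and unnamed clusters 75.0% in D3 and 62.0% in D8.

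These shares depended strongly on how cells were filtered and grouped. The streak-like class of D5 was not formed (0%) at clustering resolution 0.5, with each library clustered alone, with a stricter filter (a 10% mitochondrial limit together with a minimum of 1000 genes, not tried apart) or with the mitochondrial share taken without ribosomal RNA. The hepatic-like share of D8 was 4.19% at resolution 2.0, 9.20% with D8 clustered alone and 12.6% with the stricter filter. The endothelial-like share of D8 ranged from 0.815% at resolution 0.5 to 3.26% at resolution 2.0, with 2.80% for D8 alone. Endoderm-like cells were 4.43% of D5 when it was clustered alone. In D8, where they were 0.582%, they became 15.0% at resolution 2.0, 10.4% with D8 alone and 28.0% with the stricter filter. The name that cluster 5 met also depended on the setting. The mesenchymal-like share of D5 was 0.553% at resolution 2.0, 2.60% with the stricter filter and 0.692% with GATA6 and the introduced sequences left out. That of D3 was 0% in these 3 settings and with D3 alone, and that of D8 was 4.48% at resolution 2.0 and 4.37% with D8 alone. Erythroid-like cells, a class not formed under the reported settings, were 12.9%, 4.12% and 12.4% of D5 in these 3 settings. They were 8.09% of D5 with the mitochondrial share taken without ribosomal RNA. D5 held only 2 UMIs over 6 globin genes, so these D5 cells were not shown to be erythroid. Mesoderm-like cells were 9.98% of D5 with the stricter filter, and 13.0% of D5 and 4.31% of D8 with each library clustered alone. Endoderm-like cells of D3 were 13.2% with the stricter filter, 8.07% with D3 alone and 7.49% without cell cycle genes. Pluripotent-like cells of D3 ranged from 5.10% (D3 alone) to 46.8% (stricter filter) and 63.1% (GATA6 and the introduced sequences left out of clustering). The class was 30.5% of D5 with the mitochondrial share taken without ribosomal RNA and 17.7% of D8 with the stricter filter. The unnamed share was 34.4% of D3 and 22.4% of D8 with the stricter filter, and 30.3% of D3 with GATA6 and the introduced sequences left out. That of D5 was 43.8% with D5 alone, 16.3% at resolution 0.5 and 15.4% with the stricter filter, and ranged from 1.66% to 5.26% in the other settings.

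Among classes of at least 10 cells, the GATA6 level of D3 and D5 was highest in endoderm-like cells, and in every library it was lowest in pluripotent-like cells. Of the 5629 GATA6 UMIs of D3, 1797 were in endoderm-like cells and 3586 in the more numerous unnamed cells, at 536 CPM. In D3 the factor stood at 2525 CPM in endoderm-like, 484 CPM in cluster 5 and 38.7 CPM in pluripotent-like cells. In D5 these levels were 1496, 399 and 12.6 CPM, and streak-like cells held 90.2 CPM. The endoderm-like level was 65.2-fold above the pluripotent-like level in D3 (54.5 to 78.7) and 118-fold in D5 (71.8 to 212). On the log2 scale these ratios, 6.03 and 6.89, became 3.33 and 5.85 when GATA6 and the introduced sequences were left out of clustering, and 4.85 and 5.14 as means over cells. GATA6 was itself a leading gene of the endoderm-like cluster, so part of the contrast is built in. The streak-like level of D5 was 16.6-fold below the endoderm-like level (13.3 to 20.9), which is -4.05 on the log2 scale and -4.64 with neighbouring barcodes merged. In D8, GATA6 stood at 116 CPM in hepatic-like cells, 136 CPM in cluster 5 and 53.9 CPM in endothelial-like cells. The 10 endoderm-like cells of D8 held 17 UMIs, 157 CPM (91.5 to 252), and its 14 streak-like cells 149 CPM (93.5 to 226). A single GATA6 UMI was seen in the 131 pluripotent-like cells of D8. The D8 ratio of hepatic-like to pluripotent-like cells, 7.70 on the log2 scale, was 5.43 with GATA6 left out of clustering and 9.74 as a mean over cells. A GATA6 UMI was seen in 95.9% of endoderm-like cells of D3 and 94.8% of those of D5, at median depths of 5782 and 4479 UMIs. In pluripotent-like cells the share was 24.8% in D3, 6.98% in D5 and 0.763% in D8, at median depths of 5004, 4343 and 8061 UMIs.

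**Figure D2:**
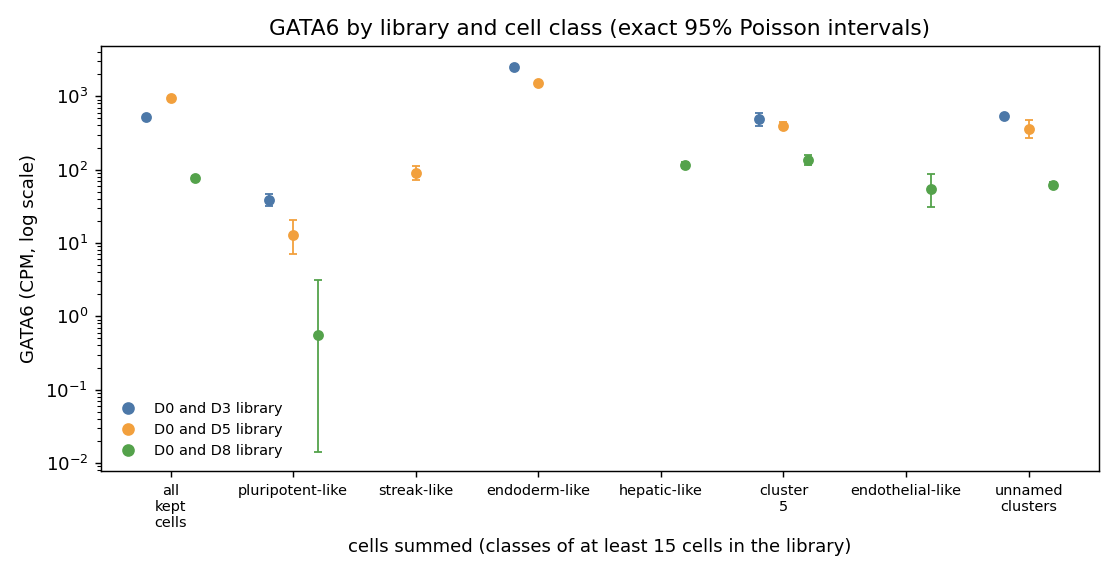
GATA6 level (CPM, log scale) in all kept cells and in each class with at least 15 cells, 1 point per library with its exact 95% Poisson interval. The endoderm-like classes of D3 and D5 stand at 2525 and 1496 CPM, and no plotted class of D8 exceeds 136 CPM.

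The introduced sequences also differed between these classes. Like GATA6, rtTA3 was among the variable genes that formed the clusters, so part of its difference is built in, whereas EYFP was not among them. The transactivator rtTA3 stood at 349 CPM in D3, 728 CPM in D5 and 521 CPM in D8. In pluripotent-like cells it was 35.7, 97.7 and 28.5 CPM, against 940 CPM in the endoderm-like cells of D3 and 832 CPM in the hepatic-like cells of D8. It was highest in cluster 5 of D3, at 1463 CPM, and in the streak-like cells of D5, at 1453 CPM. The fluorescent reporter EYFP showed the opposite order, with 73.8, 69.1 and 54.7 CPM in pluripotent-like cells. No EYFP UMI was seen in the 74 endoderm-like cells of D3, which allows up to 4.21 CPM, taken as 3 counts of the total. The exact Poisson interval there reaches 5.18 CPM. Hepatic-like cells of D8 held 9.14 CPM.

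The comparison of D5 with D3 asked what separated these libraries, whose later days fall within induction. Pluripotent-like cells were 70.8% of the named cells of D3, 18.4% of those of D5 and 20.1% of those of D8. Ratios between libraries therefore also carry the mix of cells, which the unknown share of day 0 can set. This holds for this pair and for the pairs below. Genes of plasma proteins, extracellular matrix and endoderm were higher in D5, and genes of the pluripotent state and of cell division were lower. The largest differences by the fixed rule were in the collagen gene COL3A1 (ENSG00000168542.14, chromosome 2, 188974320 to 189012746), the proteoglycan gene LUM and the aspartic protease gene CTSE. Apolipoprotein A1, fibrinogen beta and cubilin RNAs were among the 15 higher genes, and LEFTY1, L1TD1 and USP44 among the 15 lower ones.

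COL3A1 stood at 109 CPM in D5 and 0.457 CPM in D3, a ratio of 239 (102 to 739), and CTSE at 178 and 4.84 CPM, a ratio of 36.8 (28.0 to 49.4). APOA1 (ENSG00000118137.9, chromosome 11, 116835751 to 116837950) stood at 1098 and 117 CPM, 9.35-fold higher in D5 (8.81 to 9.92). HAPLN1 was 21.7-fold higher (18.8 to 25.2), FGB 22.3-fold (14.2 to 37.0), CUBN 18.4-fold (13.6 to 25.3) and DPP4 10.1-fold (8.82 to 11.7). H19, IGFBP3, HABP2, EDN3, COL6A3, LINC02413 and FOSL2 completed the higher set with ratios of 9.36 to 21.5. As means over cells, IGFBP3 was 2.32 on the log2 scale against 3.72, COL3A1 7.04 against 7.90, LUM 7.11 against 7.93, CTSE 4.49 against 5.20, FGB 3.88 against 4.48 and H19 5.18 against 4.43. Over every deposited barcode COL3A1 was 7.08. Over named clusters FGB was 5.46 and HABP2 4.26. L1TD1 stood at 546 CPM in D5 and 1914 CPM in D3, 3.51-fold lower (3.39 to 3.63), and USP44 at 99.4 and 354 CPM, 3.56-fold lower (3.29 to 3.86). LEFTY1 was 7.35-fold lower (5.43 to 10.2) and SPP1 7.21-fold lower (5.71 to 9.21). CNTN1, LNCPRESS1, TEX15, B3GALT1, MT1X, IDO1, GPM6B, POLR3G, B3GALT5, CALB1 and CNMD completed the lower set. Outside pluripotent-like clusters the lower genes lay further apart. On the log2 scale LEFTY1 was -7.79 against -2.88, LNCPRESS1 -6.43, IDO1 -5.50, SPP1 -5.48 and L1TD1 -2.63. Those cells include the unnamed ones, 1161 in D3 and 22 in D5, so this choice does not take out pluripotent-like RNA. Unnamed clusters 1 and 2 of D3 were fitted with weights of 68.5% and 57.8% on the pluripotent-like profile.

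The median log2 ratio over all genes compared was 0.10 for D5 over D3, -0.11 for D8 over D5 and -0.07 for D8 over D3, and list values are to be read against these. The pluripotent list had a median of -1.48 for D5 over D3 (interval over members -1.81 to -0.80), at percentile 0 among random lists of matched expression, with 9 of 14 members at least 2-fold lower. Outside pluripotent-like clusters this median was -2.32, with the unnamed cells still included. The definitive endoderm list stood at 1.54 with 9 of 13 members at least 2-fold higher, although LEFTY1 and CER1 were lower. The yolk-sac endoderm list stood at 1.37 (9 of 11) and the foregut and hepatic list at 1.56 (11 of 14). Plasma proteins stood at 2.54, basement membrane and collagen at 1.17, and BMP signalling at 1.36. Both cell cycle lists were lower, G1/S at -0.86 and G2/M at -0.93. Cholesterol synthesis, at 0.17, became -0.066 over named clusters, and retinoic acid and HOX genes, at 0.17, became -0.059.

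The comparison of D8 with D5 spans the withdrawal of the inducer and the change of medium. Hepatic secretory genes were far higher in D8, while genes that led the endoderm-like cluster of D5 were lower, GATA6 among them. Transthyretin, retinol-binding protein, alpha-fetoprotein and the fibrinogens headed the higher set. The lower set held OTOGL, CDH12, HSPG2, KCNJ13 and EDN3. Albumin itself was sparse, at 10.7 CPM in D8 against 1.77 CPM in D5.

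TTR (ENSG00000118271.10, chromosome 18, 31557010 to 31599021) stood at 721 CPM in D8 and 0.951 CPM in D5, a ratio of 758 (368 to 1885). AFP (ENSG00000081051.7, chromosome 4, 73431138 to 73456174) stood at 1291 and 8.16 CPM, a ratio of 158 (123 to 208), and its log2 ratio of 7.31 was 6.22 as a mean over cells. TTR, at 9.57, was 10.48 as a mean over cells and 8.93 over every deposited barcode. APOB (ENSG00000084674.14, chromosome 2, 21001429 to 21044073) stood at 3309 and 144 CPM, 23.0-fold higher (21.6 to 24.5). FGB was 42.6-fold higher (38.0 to 47.9), FGA 55.9-fold (48.3 to 65.1) and RBP4 244-fold (124 to 565). SERPINA1 rested on 1 UMI in D5 and AHSG on 2, with ratios of 739 (133 to 29228) and 220 (60.6 to 1816). On the log2 scale SERPINA1 was 8.10 over every barcode against 9.53, AHSG 8.71 outside pluripotent-like clusters, TF 4.27 by mean over cells and ABCC2 5.30 outside pluripotent-like clusters. FGG, AKR1B10, VTN and LGALS3 also belonged to the higher set. OTOGL (ENSG00000165899.11, chromosome 12, 80099537 to 80380879) was 25.6-fold lower in D8 (18.8 to 35.8), CDH12 17.3-fold lower (12.7 to 23.96) and HSPG2 13.3-fold lower (11.6 to 15.3). BRDT, APOLD1, NPY, COCH, LINC02582, CST1, PLCXD3, CLVS2 and COL19A1 completed the lower set. By mean over cells, APOLD1 was -2.65, NPY -2.51 and COCH -2.30 on the log2 scale.

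Among the lists, plasma proteins had a D8 over D5 median of 4.81 (3.15 to 5.83), with 17 of 20 members at least 2-fold higher. The foregut and hepatic list stood at 2.60 (-0.40 to 5.41), and at 4.52 when members needed 20 CPM. Its transcription factor HNF4A was 2.11-fold higher (1.94 to 2.29), whereas FOXA2 was 1.87-fold lower (1.71 to 2.04). Endothelial genes stood at 1.53 and mesenchymal genes at 1.21. Streak genes stood at -1.73, GATA factors at -1.79 and BMP signalling at -0.57. WNT signalling stood at -0.99, and at -0.29 when members needed 20 CPM. The pluripotent list stood at 0.41, with 13 of 14 members within 2-fold.

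D8 against D3 compares the latest library with the earliest. Several hepatic and stromal genes that were high in D8, such as FGB and COL3A1, rested on few UMIs in D3, whereas APOB stood there at 24.5 CPM and APOA1 at 117 CPM. D3 was higher in GATA6 and in a set of genes that included BRDT and the imprinted gene PEG10. Of this set, BRDT was a leading gene of unnamed cluster 1, and PEG10, FBN2 of unnamed clusters 1 and 2. These clusters held 657 and 504 of the D3 cells. Plasma protein genes were higher in D8 without exception. SERPINA1 was not detected in D3 and was at least 367-fold higher in D8, computed against a floor of 3 UMIs.

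FGB (ENSG00000171564.11, chromosome 4, 154562956 to 154571086) stood at 1736 CPM in D8 and 1.83 CPM in D3, a ratio of 950 (615 to 1555), which on the log2 scale was 11.01 over named clusters. AFP was 239-fold higher (186 to 315), APOB 135-fold (120 to 153), COL3A1 1422-fold (609 to 4381), FGA 325-fold (244 to 445) and AKR1B10 131-fold (90 to 199). TTR rested on 4 UMIs in D3, RBP4, LUM and DDC on 3 each, and PLA2G12B on 2. Their ratios were 1972 (770 to 7237) for TTR, 967 (331 to 4691) for RBP4, 625 (214 to 3033) for LUM, 292 (99.6 to 1417) for DDC and 251 (69.2 to 2077) for PLA2G12B. FGG and IGFBP3 also belonged to the higher set. On the log2 scale, APOB and AKR1B10 were 7.79 each and FGG 8.89 over named clusters, RBP4 was 11.17 outside pluripotent-like clusters, and COL3A1 was 9.75 over every barcode. Means over cells gave LUM 8.61, DDC 7.00 and PLA2G12B 7.31. BRDT was 13.1-fold lower in D8 (9.93 to 17.6) and PEG10 3.52-fold lower (3.36 to 3.69). COL19A1, CLVS2, FBN2, PIEZO2, FAM184A, FEZ1, DUSP4, FAM129A, GALNT17, THADA and HSPG2 also belonged to the lower set, with GATA6. Several of these were closer over named clusters, with CLVS2 at -1.34, FBN2 at -1.15, PIEZO2 at -0.96, FAM184A at -1.03 and DUSP4 at -0.83 on the log2 scale. HSPG2 was -2.34 by mean over cells.

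For D8 over D3 the plasma protein list stood at 7.10 (5.29 to 8.35) with 20 of 20 members at least 2-fold higher, and the foregut and hepatic list at 4.88 (0.72 to 7.90). The latter was 5.68 with a 20 CPM minimum and 4.21 over named clusters. Drug metabolism and bile acid genes stood at 4.94 over 5 measured members, endothelial genes at 3.52 and mesenchymal genes at 1.62. The yolk-sac endoderm list stood at 2.23, and at 1.59 over named clusters. The pluripotent list stood at -0.94, with G1/S at -0.69 and G2/M at -0.73. Definitive endoderm and cholangiocyte genes, both at 0.62, stood at 1.22 and 1.25 over named clusters. WNT signalling, at -0.50, became 0.18 with a 20 CPM minimum, and GATA factors, at 0.17, became -0.10 outside pluripotent-like clusters and 0.77 over named clusters.

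**Figure D3:**
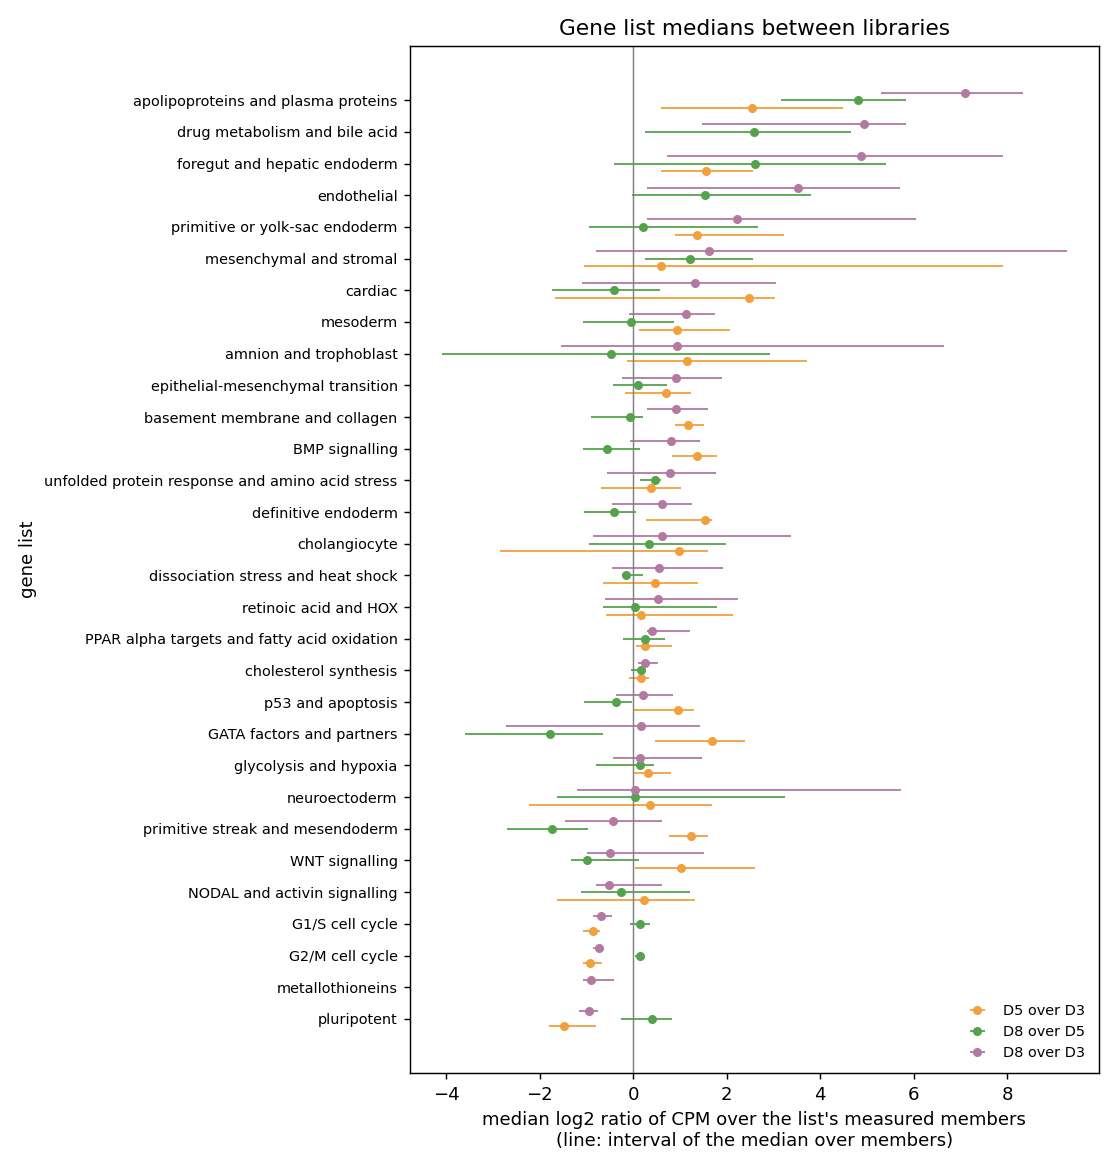
Median log2 ratio of CPM over the measured members of each gene list, for the 3 pairs of libraries, with lines for the interval of the median over members. Plasma proteins lie farthest to the right (7.10 for D8 over D3) and the GATA factors (-1.79) and streak genes (-1.73) for D8 over D5 farthest to the left.

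Because the study concerns an agonist of the nuclear receptor PPAR alpha, its targets were followed through the series. As a list they differed little between libraries, while a few members differed widely. The list median was 0.24 for D5 over D3 (percentile 73.5), 0.26 for D8 over D5 (percentile 100) and 0.41 for D8 over D3 (percentile 99.7), where 6 of 18 members were at least 2-fold higher. PPARA itself stood at 19.4 CPM in D3, 51.9 CPM in D5 and 44.9 CPM in D8. Among the members that differed widely, FABP1 stood at 33.9 CPM in D8 with 2 UMIs in D5. CPT1A was 2.84-fold lower in D8 than in D3 (2.18 to 3.71). In D8 the list stood 0.97 higher in hepatic-like than in pluripotent-like cells, with 8 of 16 members at least 2-fold higher.

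Pluripotent-like cells are the class that every library can share, since each label names day 0. The class was named by its pluripotent markers, so closeness of these between libraries is partly built in. All 14 members of that list were within 2-fold in each pair, with medians of -0.08 for D5 over D3, 0.09 for D8 over D5 and 0.07 for D8 over D3. Among lists that did not name the class, plasma proteins stood at 2.44 for D8 over D5 (1.48 without members at a count of 0) and 2.98 for D8 over D3. APOB stood at 67.6 CPM in these cells in D8, against 3309 CPM over all kept cells, so free RNA is an open source. GATA6 was 3.06-fold lower in the pluripotent-like cells of D5 than in those of D3 (1.79 to 5.63), with the caution that GATA6 helped form the clusters. The class pools clusters 0 and 4, which held 106 and 168 cells in D3 and 27 and 102 in D5. GATA6 stood at 35.3 CPM in D3 (28.2 to 43.7) and 5.53 CPM in D5 (1.51 to 14.2) in cluster 0. In cluster 4 it stood at 47.7 CPM (34.5 to 64.3) and 23.7 CPM (11.8 to 42.4), with intervals that overlap.

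Endoderm-like and pluripotent-like cells of the same library differed in matrix, signalling and cell division. Fibronectin was among the most abundant RNAs of endoderm-like cells, at 17193 CPM in D3 against 415 CPM in pluripotent-like cells, 41.4-fold higher (39.1 to 43.8), and 51.3-fold higher in D5 (46.0 to 57.4). AHNAK was 57.6-fold higher in D3 (49.2 to 67.8), RSPO3 51.6-fold (37.0 to 73.9) and ALDH1A1 52.4-fold (32.8 to 88.7). In D5, RSPO3 was 240-fold higher (93.6 to 881). ESRG was 23.3-fold lower in endoderm-like cells of D3 (14.1 to 41.7) and 329-fold lower in those of D5 (150 to 901). The BMP signalling list stood 3.03 higher in D3, with 12 of 13 members at least 2-fold higher, and 3.23 higher in D5. Basement membrane and collagen genes stood 3.24 and 2.75 higher. In D5, cluster 5 was set apart from endoderm-like cells by HAPLN1, 265-fold higher (203 to 353), and CDH11, 417-fold higher (201 to 1043), and streak-like cells by ESRG, CAVIN1 and WNT5A.

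In D8, hepatic-like cells exceeded pluripotent-like cells in genes that had not named them. Such genes were not kept out of the clustering, so part of these differences, and of those within D3 and D5 above, may be built in. MTTP was 100-fold higher (66.9 to 159), GSTA1 129-fold (59.0 to 351) and ANPEP 126-fold (57.6 to 343). Plasma protein members outside the naming markers stood 4.45 higher, drug metabolism genes 4.90 higher over the 5 of 23 members measured, and BMP signalling 3.37 higher, while metallothioneins stood at -5.73. Against cluster 5, hepatic-like cells were higher in cholesterol synthesis, by a median of 1.10 with 10 of 18 members at least 2-fold higher. H19 was 244-fold lower in hepatic-like cells than in cluster 5 (167 to 372) and CDH11 155-fold lower (89.8 to 293). Endothelial-like cells, compared with cluster 5, were marked by TFPI2, 136-fold higher (73.0 to 286).

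Cell division genes were low in the endoderm-like cells of D3 and D5 and in the hepatic-like cells of D8, and higher in the other named classes. The few endoderm-like cells of D8 were not low, with a G2/M sum of 3600 CPM (2704 to 4697) over 10 cells thinned to 1500 UMIs. In the endoderm-like over pluripotent-like contrast the G2/M list stood at -2.55 in D3 (-1.89 with neighbouring barcodes merged) and -3.77 in D5, and in the hepatic-like over pluripotent-like contrast of D8 at -4.21. All 16 measured members were at least 2-fold lower in each contrast. The G1/S list stood at -2.36, -2.97 and -3.05. Within D5, streak-like cells stood 4.22 above endoderm-like cells for G2/M and cluster 5 stood 3.46 above them. MKI67 was at 33.1 CPM in the endoderm-like cells of D5, 318 CPM in pluripotent-like and 613 CPM in streak-like cells. With cells thinned to 1500 UMIs, the G2/M list summed to 335 CPM in the endoderm-like cells of D5, 3959 CPM in pluripotent-like and 7605 CPM in streak-like cells. The pluripotent-like level of D5 was 11.8-fold above the endoderm-like level (10.0 to 14.0). At least 2 G2/M UMIs were seen in 10.3% of endoderm-like and 92.2% of pluripotent-like cells of D5, and in 10.2% of hepatic-like and 96.9% of pluripotent-like cells of D8. Cell cycle genes were not kept out of the clustering, so part of these differences between classes may be built in. The differences were not recomputed with cell cycle genes left out of clustering.

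**Figure D4:**
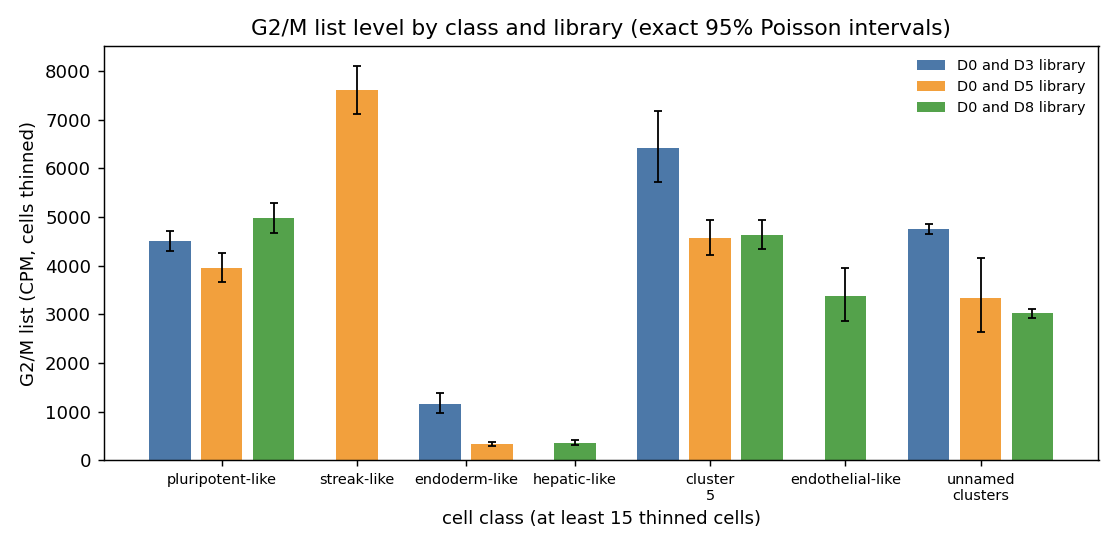
Summed G2/M list level (CPM, cells thinned to 1500 UMIs) by class and library, for classes of at least 15 thinned cells, with exact 95% Poisson intervals. Endoderm-like cells of D5 (335 CPM) and hepatic-like cells of D8 (361 CPM) stand lowest, and streak-like cells of D5 (7605 CPM) highest.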

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

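The second form of the mixture tests and the test of GATA6 against rtTA3 were chosen after the results had been seen.

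The hygromycin resistance sequence, outside the main comparisons, had 4 UMIs over every deposited barcode of D3 and 5 over those of D8, and is absent from the D5 file. These counts were picked out only because they exceed the 3 UMIs that a count of 0 allows. Kept cells held 3 and 4 of them, there is no control library, and nothing is drawn from them. Pairs of barcodes that differ by 1 base numbered 109 in D3, 527 in D5 and 153 in D8, where random barcodes would give 4.29, 4.11 and 4.29. Also, 2 lists had opposite signs for endoderm-like over pluripotent-like cells in D3 and D5. The epithelial-mesenchymal transition list stood at -0.41 in D3 and 0.13 in D5, and the unfolded protein response list at -0.35 and 0.48. Neither difference between libraries was tested.

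The first pattern is that clusters without a name held 75.0% of the kept cells of D3 and 62.0% of those of D8. In unnamed D8 barcodes the cluster 5 gene set stood 11.4-fold (10.4 to 12.5) above the higher of the pluripotent-like and hepatic-like classes. By the rule as written, this counted against a passage of cells from pluripotent-like to hepatic-like as the whole source. But the set was picked in these data for being low in both classes, and free RNA could bring it into passing cells. That test therefore could not decide. At 1500 UMIs per barcode the set held 4.61 UMIs in unnamed barcodes, 0.674 in pluripotent-like and 0.335 in hepatic-like cells, a smaller distance in the same direction. A passage of cells, RNA of many cells under 1 barcode and pairs of cells all stay open. In the first test 0.284% (0.0587 to 0.829) of unnamed D8 barcodes held all 3 exclusive sets, which by the rule as written would have counted against many cells and for pairs, but its pluripotent set had 1 gene that only 1.55% of pluripotent-like cells held, so that test could not decide. In a second form, 1.23% (0.658 to 2.1) of unnamed D8 barcodes and 6.97% (5.57 to 8.61) of unnamed D3 barcodes held all 3 sets, the latter 4.98 times the share of drawn pairs. Drawn pairs gave 0.1% in D8 and 1.4% in D3, so the distance was larger in D8, while drawn mixtures of 3 classes gave 1.95% in D8 and 55.8% in D3; the bound for excluding pairs was made stricter after this value was seen, and drawn cells are an assumed model, so no explanation was excluded by it.

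The second pattern is the excess of barcodes 1 base apart. Of 200 such pairs of kept D5 cells in 1 cluster, 146 lay in clusters with enough cells to test, and of these 86.3% (79.6 to 91.4; 126 of 146) were more alike than 95% of random pairs of their cluster, and 58.0% (40 of 69) and 78.9% (105 of 133) were in D3 and D8. This is consistent with 1 bead read under several barcodes, a technical source, and the 16 D5 barcodes with the same first 10 bases have that form. The number of cells may therefore be overstated, and each interval on a share too narrow, in D5 above all. No biological explanation was tested.

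The third pattern is that pluripotent-like cells held few rtTA3 UMIs, 117 in D3, 116 in D5 and 51 in D8, beside 127, 15 and 1 GATA6 UMIs. Free RNA of the library as the only source of both would keep them in the ratio of the other cells, if it had their content. The GATA6 to rtTA3 ratio in pluripotent-like cells was 0.730 times (0.607 to 0.870) that of the other cells in D3, 0.0978 times (0.0547 to 0.161) in D5 and 0.131 times (0.00331 to 0.730) in D8. The test is void, because GATA6 and rtTA3 were among the genes that formed the clusters and the content of free RNA was not measured, so this explanation stays open. The test was first made on D5 alone and then extended to the other libraries. A low expression of the transactivator in some cells, or cells of day 0 that had met no inducer, also stay open and were not tested.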

How the results depend on the processing

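Alternatives that merged neighbouring barcodes, took named clusters only, left GATA6 and the introduced sequences out of clustering, or took the mitochondrial share without ribosomal RNA were chosen after the data had been seen. Where a value moved, the cause was not tested, except that settings with fewer genes or cells use less data by construction. No alternative reversed a named gene: of 534 recomputed log2 ratios, 413 stayed within their counting interval and 121 moved. Of 324 recomputed list medians, 294 stayed, 15 moved and 15 reversed. Of 110 recomputed class shares 74 stayed and 36 moved, and of 30 recomputed values between classes 24 stayed and 6 moved. Of 18 recomputed GATA6 levels 10 stayed and 8 moved.

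Among class shares, with the 10% mitochondrial limit and 1000 genes, pluripotent-like cells were 46.8% of D3 and 17.7% of D8, endoderm-like cells 13.2% of D3 and 28.0% of D8, and hepatic-like cells 12.6% of D8. With each library clustered alone, pluripotent-like cells were 5.10% of D3, endoderm-like cells 8.07% of D3, 4.43% of D5 and 10.4% of D8, and hepatic-like cells 8.71% of D5 and 9.20% of D8. At resolution 2.0, D8 held 4.19% hepatic-like and 15.0% endoderm-like cells. Leaving GATA6 and the introduced sequences out put pluripotent-like cells at 63.1% of D3. With merged barcodes, D3 held 14.9% pluripotent-like and 7.14% endoderm-like cells. With 1000 variable genes, pluripotent-like cells were 20.2% of D3. Endoderm-like cells of D3 were 7.49% without cell cycle genes, 6.38% with doublets kept and 6.67% with thinned cells. Without ribosomal RNA in the mitochondrial share, D5 held 30.5% pluripotent-like and 46.4% endoderm-like cells.

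GATA6 kept its order of D5 over D3 over D8 in each alternative. Its level in D3 was 566 CPM as a mean over cells, 576 thinned and 481 over named clusters. In D5 it was 891 over every barcode and 893 by median-of-ratios scaling. In D8 it was 71.4 as a mean over cells, 70.5 thinned and 91.5 over named clusters. Its log2 ratio for D5 over D3 was 0.81 by median-of-ratios, 0.77 as a mean over cells, 0.79 over every barcode, 0.64 outside pluripotent-like clusters and 0.99 over named clusters. For D8 over D5 it was -3.44 by TMM and by median-of-ratios, -3.76 as a mean over cells and -3.38 over named clusters. For D8 over D3 it was -2.60 by TMM, -2.63 by median-of-ratios, -2.99 as a mean over cells, -3.02 outside pluripotent-like clusters and -2.39 over named clusters.

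Without the filter on low counts, 12 of the 30 named genes were shared for D5 over D3, 16 for D8 over D5 and 17 for D8 over D3. Over named clusters, 17 were shared for D8 over D3.

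Outside pluripotent-like clusters, with the unnamed cells still included, the pluripotent list stood at -2.32 for D5 over D3 and -1.17 for D8 over D3. Over named clusters it stood at -1.41 for D8 over D3. The definitive endoderm list was 1.72 for D5 over D3 over named clusters. The following medians reversed. Over named clusters, cholesterol synthesis was -0.066 and retinoic acid and HOX -0.059 for D5 over D3. For D8 over D5, mesoderm was 0.10 by TMM and 0.062 over named clusters, basement membrane and collagen 0.080 and 0.052, G2/M -0.041 and dissociation stress 0.060 over named clusters. Neuroectoderm for D8 over D5 was -0.43 with a 20 CPM minimum, -0.50 outside pluripotent-like clusters and -0.22 over named clusters, and for D8 over D3 -0.091 outside those clusters and -0.81 over named clusters. For D8 over D3, WNT signalling was 0.18 with a 20 CPM minimum and GATA factors -0.10 outside pluripotent-like clusters.

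Between classes, GATA6 in endoderm-like over pluripotent-like cells was 3.33 in D3 and 5.85 in D5 with GATA6 left out of clustering, and 4.85 and 5.14 as a mean over cells. With merged barcodes, the G2/M list was -1.89 for that contrast in D3, and GATA6 in streak-like over endoderm-like cells of D5 was -4.64. The D8 contrast of GATA6 rests on 1 UMI in pluripotent-like cells, and a count this small limits its precision.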

Other observations

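The comparisons of 1 class between libraries given here were chosen after values had been seen. In endoderm-like cells, CTSE was 10.7-fold higher in D5 (6.89 to 17.6), GPC3 5.73-fold (4.41 to 7.60), CUBN 8.34-fold (4.63 to 16.8), MTTP 4.56-fold (3.02 to 7.25), APOB 4.06-fold (2.94 to 5.78) and APOA1 3.55-fold (3.20 to 3.95). FBN2 was 5.87-fold lower (4.98 to 6.92), COL1A2 7.02-fold lower (4.25 to 11.6) and PEG10 3.59-fold lower (3.26 to 3.95). GATA6 was 1.69-fold lower in these cells (1.60 to 1.78), although it was higher in D5 over all kept cells. Because GATA6 helped form the clusters and was a leading gene of the endoderm-like cluster, part of this difference may be built in. The plasma protein list stood at 1.71 and the G2/M list at -1.17, with D3 represented by 74 cells.

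Cluster 5 held cells of every library with unlike content. COL3A1 was not detected in its 32 cells of D3, and stood at 979 CPM in D5 and 4072 CPM in D8. Its D3 cells held the streak and mesoderm genes MIXL1 (240 CPM), EOMES (176 CPM), TBXT (63.6 CPM) and HAND1 (700 CPM). The mesenchymal list stood 3.02 higher in D8 than in D3 within this cluster. Hepatic transcripts were also seen in it in D8, with APOB at 301 CPM and FGB at 172 CPM. Globin UMIs of D8 were held by few barcodes, 3 barcodes holding 628 of the 646.

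Mean profiles of the unnamed clusters were close to weighted sums of the named profiles of their library, with correlations across genes of 0.982 and 0.974 for clusters 1 and 2 of D3 and 0.984 and 0.917 for clusters 8 and 10 of D8. Cluster 8 was fitted by 39.3% pluripotent-like, 46.1% hepatic-like and 13.2% cluster 5. Genes are not independent replicates, and these fits do not tell free RNA from pairs of cells.

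Pluripotent-like cells of different libraries were also compared for spread. Their median absolute log2 difference between libraries was 1.22 times (D5 over D3), 1.19 times (D8 over D5) and 1.29 times (D8 over D3) that of draws from 1 profile. Cluster 5 gave up to 1.85 times. A first reading of these values as 1 shared population was set aside, because single libraries give no measure of the spread between preparations.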
